A study of Mus musculus with 2 samples.

How the data were processed

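RNA of single cells was measured in 2 libraries from mouse aortic allografts, 1 taken 2 weeks and 1 taken 4 weeks after grafting. Per the labels' protocols, the adventitia of harvested grafts was separated from the media and neointima, the tissue was minced and digested with papain, and live Hoechst-positive (nucleated) single cells were sorted. Libraries were made with 10x Chromium 3' v2 chemistry and sequenced as 150-base paired ends on a NovaSeq, per the labels' protocols. The deposited values are whole-number counts of UMIs per gene and cell barcode, the filtered matrices of the authors' pipeline. Cell Ranger 2.2.0 and the genome build mm10 were named per the submitters' processing notes, and the annotation behind the counts is not given in the sources used here. Each library was taken as 1 sample, and its group and time came from the labels. The labels name no animal, so the number of grafts behind a library is unknown.

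The files listed 27998 genes in both libraries, and 27645 of these identifiers matched the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Gene positions are taken from it, 1-based. The lowest UMI total of a barcode was 2354 at 2 weeks and 1949 at 4 weeks, so the files differ in the depth at which barcodes were kept upstream. Barcodes with at least 300 detected genes and at most 10% mitochondrial UMIs were kept, which removed 8 at 2 weeks and 30 at 4 weeks.

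Doublets were scored per library with scrublet as run by scanpy, at an expected rate of 0.04 and seed 0. Its automatic threshold marked 3 barcodes at 2 weeks (0.0687%) and 3 at 4 weeks (0.0654%), which is under the working minimum of 0.5%. The fallback fixed for that case, the top 4% of the score, was used instead. Tied scores made it remove 202 (4.63%) and 190 (4.14%) barcodes. The fallback also takes rare cell types with high scores, among them barcodes with contractile genes.

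Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch key, and 30 principal components, 15 neighbours and Leiden resolution 1.0 were used. A cluster was named only from 25 fixed marker sets, with at least 3 markers detected in at least 10% of its cells at 2 times the median cluster, and is called X-like. Names rest on these markers and not on an annotation by the authors. A cluster whose 10 leading genes held more markers of another class than of its own was left unnamed. This held for cluster 7, which met the T cell set with 9 markers detected. Its 10 leading genes held 0 markers of the T cell sets and 1 of the dendritic set.

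Shares of kept cells carry exact Clopper-Pearson intervals at a confidence level of 95%, and beside a share of 0 the limit is that of 3 counts of the total. Counts were summed per class and library and expressed as CPM of the class total. The ratio of 4 weeks over 2 weeks carries an exact conditional binomial interval, and a count of 0 was set to a floor of 3 counts to give a bound. Classes with at least 50 cells in each library were compared, which left 9. A list member counted as measured with at least 20 UMIs over both libraries. Of 497 entries in 36 fixed gene lists, 484 were found. The median of a list was ranked among 10000 random lists of the same size matched on mean expression, as a description of these libraries. No test across samples was possible with 1 library per time, and no p-value was computed from cells.

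Genes were named by a rule: in each compared class, the 10 highest and 10 lowest ratios, ranked by the interval bound nearest 0, among genes with at least 50 CPM in 1 library, 50 UMIs in all and a class level of at least 0.25 of the library's. The rule left out mitochondrial, ribosomal protein, haemoglobin, sex-linked, receptor variable and predicted genes. It also took the 3 members with the most UMIs of each reported list, and list members with a log2 ratio of size 1 or more whose interval excluded a 1.5-fold difference. Of these the text names examples, and which lists and examples it names was decided after their values were seen. Clusters, filters, marker sets, lists, the naming rule and most of the alternatives were fixed before the data were examined.

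For shares of cells with a UMI, every cell was thinned to 1000 UMIs by hypergeometric sampling. No cell was left out, since the shallowest barcode held 1949. After the data were seen, each ratio was also set against the median ratio of the same gene over the other compared classes, with at least 3 of them expressing it. Transcript length was that of the longest coding transcript in GENCODE M21.

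The ratio, list and subtraction steps were tested on simulated data. Counts were drawn for the real genes of each class with 200 of them altered. Intervals covered the true ratio for 95.8% to 96.7% of genes over the 9 classes, and all 20 genes named by the rule were truly altered ones in each class. In that check the counts held counting error only and no difference shared by classes. It therefore does not show that a gene named in the real data differs in its class alone. Of genes altered 1.5-fold, 100% were recovered in macrophage-like cells (10697 genes) and 46.3% in cluster 7 (5308 genes). Of genes altered 2-fold the shares were 100% and 74.6%.

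Alternatives covered the cell filter, doublet removal, cluster resolution, clustering each library on its own, assignment of each cell alone, variable genes, scaling, weighting of cells, proliferating cells, and UMI minimum and thinning depth. Added after the data were seen were a common UMI minimum, the subtraction of other classes, length-matched random lists and a set of 10 cycle genes. Also added then were variable genes without those that differed at least 1.5-fold in the median over classes. Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9, with R 4.3.3 and edgeR 4.0.16 for the trimmed-mean (TMM) factors.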

Results

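Single-cell transcriptomes were recorded from mouse aortic allografts, segments of aorta transplanted between animals that differ in their tissue antigens. Grafts were examined 2 and 4 weeks after transplantation, and each time is represented by 1 library. The 2-week library held 4374 cell barcodes with 31904325 unique molecular identifiers (UMIs), which count captured RNA molecules, and the 4-week library held 4615 barcodes with 20793894 UMIs. The median was 6169 UMIs per barcode at 2 weeks and 3185 at 4 weeks. After filtering and doublet removal 4164 and 4395 cells were kept, with medians of 1789.5 and 1270 detected genes. With 1 library per time there is no replicate spread and no test across samples. All differences compare these 2 libraries, all intervals are 95% intervals that cover counting error only, and differences in expression are log2 ratios of 4 weeks over 2 weeks.

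The first comparison asked which cell classes made up the graft at each time. Macrophage-like cells, tissue phagocytes, were the most frequent class at 2 weeks and far less frequent at 4 weeks: 43.5% (42.0 to 45.0) at 2 weeks and 9.81% (8.94 to 10.7) at 4 weeks. B cell-like cells, the antibody lineage, made up 4.20% (3.61 to 4.86) at 2 weeks and 25.9% (24.6 to 27.2) at 4 weeks, a ratio of 6.16. CD8 T-like cells, the cytotoxic arm of the T cell response, made up 25.3% (23.9 to 26.6) at 2 weeks and 30.2% (28.9 to 31.6) at 4 weeks, a difference of 4.95 percentage points that was 16.2 with each library clustered on its own. The T-like classes together with cluster 7, an unnamed cluster with T cell markers, took 35.2% (33.8 to 36.7) at 2 weeks and 46.1% (44.6 to 47.6) at 4 weeks.

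Among the smaller classes, monocyte-like cells, the blood-derived precursors of macrophages, made up 6.51% (5.78 to 7.30) at 2 weeks and 4.44% (3.85 to 5.09) at 4 weeks. That difference of -2.07 percentage points fell to -0.365 (-1.35 to 0.620) with a looser cell filter and -1.02 (-2.06 to 0.0270) with other variable genes, and was -11.9 with each cell assigned alone. With each library clustered on its own it was -6.32, the whole 2-week share, since no cluster of the 4-week library was named monocyte-like. CD4 T-like cells, the helper and regulatory lineage, made up 5.81% (5.12 to 6.57) at 2 weeks and 4.16% (3.59 to 4.80) at 4 weeks. The CD4 difference was 0.00515 percentage points when each cell was assigned alone, -0.489 points without doublet removal and -2.79 with each library clustered on its own, against -1.65 as reported. Cluster 7, led by the genes Lef1, Dapl1, Tcf7 and Ccr7, took 1.83% (1.44 to 2.28) at 2 weeks and 8.71% (7.90 to 9.59) at 4 weeks. Natural killer (NK)-like cells made up 2.74% at 2 weeks and 3.91% at 4 weeks, dendritic-like cells 2.16% at 2 weeks and 1.71% at 4 weeks and plasmacytoid dendritic-like cells 2.04% at 2 weeks and 2.12% at 4 weeks. Neutrophil-like cells made up 0.600% at 2 weeks and 1.30% at 4 weeks, and plasma cell-like cells, the antibody secretors, 0.504% at 2 weeks and 1.39% at 4 weeks.

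Cells of the vessel wall were scarce in both libraries. Fibroblast-like cells made up 0.985% (0.707 to 1.33) at 2 weeks and 3.21% (2.71 to 3.77) at 4 weeks, which is 41 and 141 cells. Without doublet removal they numbered 67 of 4366 at 2 weeks and 151 of 4585 at 4 weeks. Endothelial-like cells, the inner vessel lining, numbered 42 at 2 weeks and 3 at 4 weeks, shares of 1.01% and 0.0683%. Lymphatic endothelial-like cells made up 0.504% at 2 weeks and 0.0910% at 4 weeks. No cluster qualified as smooth muscle-like, the main cell of the arterial media, although the doublet step removed barcodes rich in contractile genes. The preparation can set such shares: the adventitia was parted from the media and neointima, the tissue was digested with papain, and live nucleated cells were sorted. The labels do not say which of the parted layers entered each library. The 2 libraries also differed in depth, with median UMIs of 8548 and 7273 in macrophage-like, 3669 and 2824 in CD8 T-like and 3350 and 2615 in B cell-like cells at 2 and 4 weeks.

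**Figure D1:**
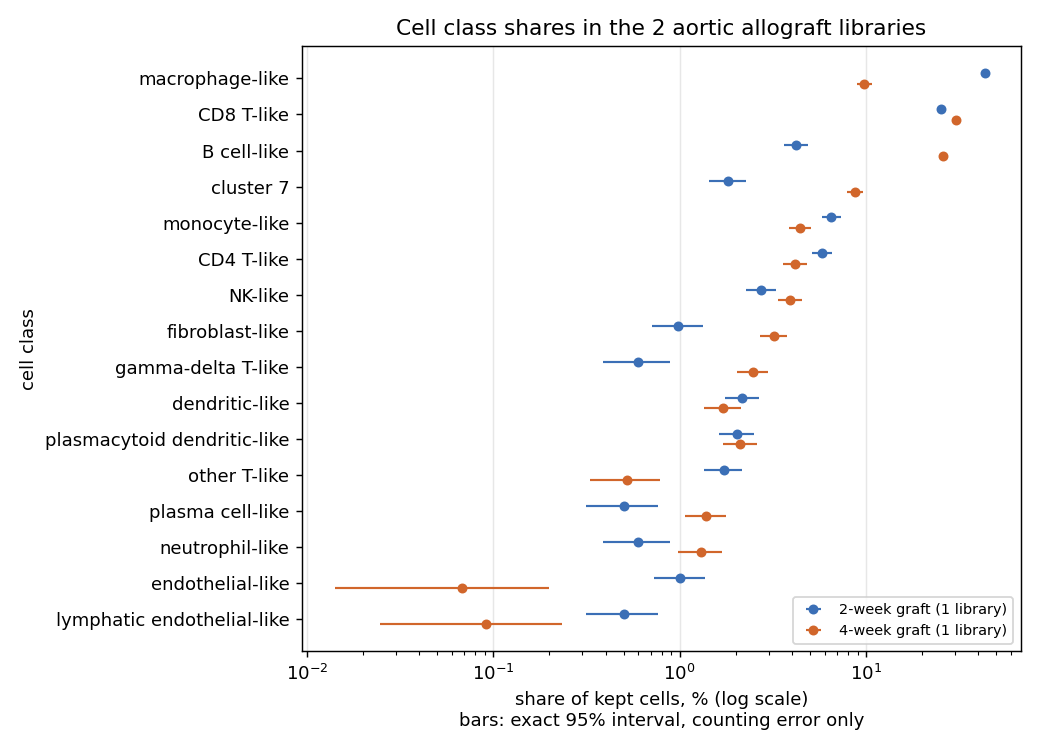
Share of kept cells (per cent, horizontal axis) of each cell class in the 2-week and 4-week libraries, with exact 95% intervals that cover counting error only. Macrophage-like cells stood at 43.5% and 9.81%, B cell-like cells at 4.20% and 25.9%.

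Expression was compared within each of the 9 classes that had at least 50 cells in both libraries. Of 1838 genes expressed in all of them, 88 were at least 1.5 times higher at 4 weeks in all 9 classes and 4 at least 1.5 times lower, and 87 and 4 of these had at least 0.25 of a library's CPM in every class. Among the higher was Tagap, a GTPase-activating protein of lymphocytes, with a median log2 ratio of 2.65, between 1.57 and 3.47 over the classes. Txnip, an inhibitor of thioredoxin, lay at 1.93, between 1.27 and 2.77, and Fosb, an immediate early transcription factor, at 1.72, between 0.80 and 2.24. Also among them were Eef2, the translation elongation factor, at 1.84, between 1.75 and 2.04, and Pabpc1, the poly(A)-binding protein, at 1.44, between 1.34 and 1.56. Among the lower was H2-K1, an MHC class I heavy chain, at -0.71, between -1.10 and -0.62.

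Over the same 1838 genes, Pearson's r of the log2 ratios between classes lay between 0.621 and 0.887 over 36 class pairs, with a median of 0.744, and Spearman's coefficient between 0.543 and 0.846. These correlations are across genes, which are not independent replicates. The log2 ratio also went with transcript length, with a Spearman coefficient of 0.544 over 1812 genes, and the median was -0.21 in the fifth with the shortest transcripts (348 to 1068 nt) and 0.38 in the fifth with the longest (3460 to 21452 nt). Many of the within-class differences below are in part shared by other classes, while others run against them, and the log2 ratio in the other classes is given beside some of them. Of genes that met the naming minimums and differed at least 2-fold, few stood at least 2-fold beyond the other classes in the same direction. These were 6 of 359 (1.67%) in macrophage-like, 17 of 397 (4.28%) in CD8 T-like and, at the highest, 49 of 292 (16.8%) in cluster 7 cells. This counts genes that at least 3 other classes expressed. Scaling with trimmed-mean factors moved all log2 ratios of a class by between -0.43 in macrophage-like cells and 0.025 in cluster 7.

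**Figure D2:**
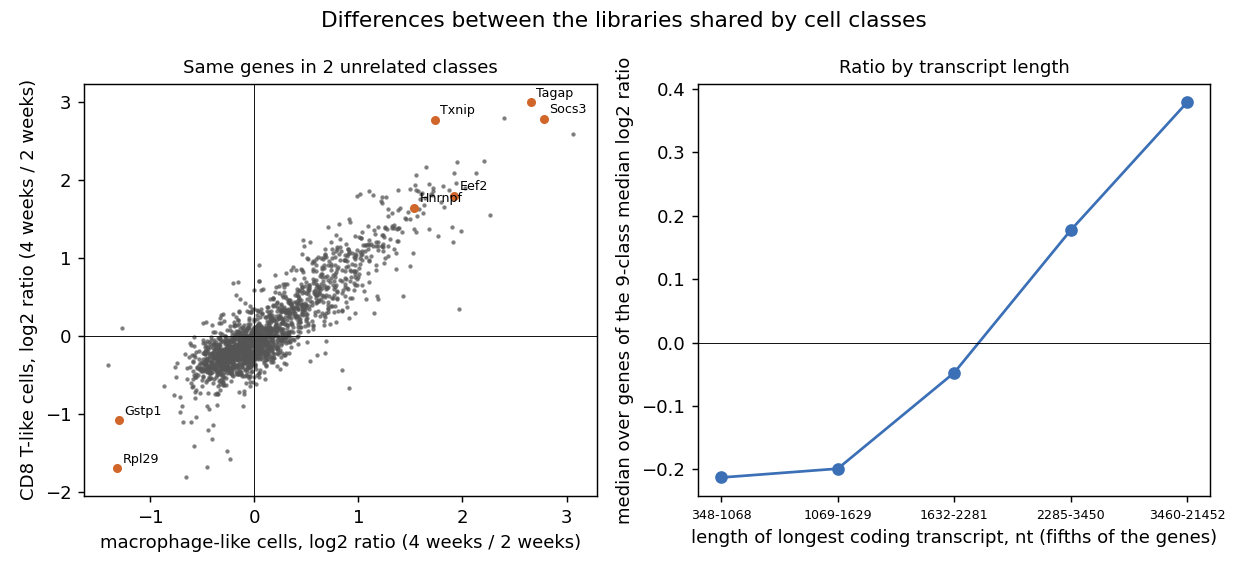
Log2 ratio of 4 weeks over 2 weeks in macrophage-like cells (horizontal axis) and CD8 T-like cells (vertical axis), 1 point for each of 1838 genes, which are not independent replicates, and the median log2 ratio in 5 equal groups of genes by transcript length (nt). Tagap and Txnip lie high on both axes of the left panel, and the medians run from -0.21 to 0.38 on the right.

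Immediate early genes, which cells switch on within minutes of stimulation or of tissue digestion, had a median above 0 in all 9 classes. The median of this list was 1.202 in macrophage-like, 1.36 in CD8 T-like, 1.06 in CD4 T-like, 0.99 in dendritic-like, 0.69 in NK-like, 0.56 in monocyte-like, 0.50 in B cell-like and 0.45 in plasmacytoid dendritic-like cells and 0.44 in cluster 7. Members at least 1.5 times higher at 4 weeks numbered from 4 of 17 in cluster 7 to 16 of 19 in macrophage-like cells, and 1 in cluster 7 was at least 1.5 times lower. The lowest percentile was 99.39 among 10000 random lists matched on expression and 96.8 among lists matched on transcript length as well. Minus the other classes the median turned below 0 in B cell-like (-0.32), NK-like (-0.0072), monocyte-like (-0.21) and plasmacytoid dendritic-like cells (-0.21) and in cluster 7 (-0.41). Junb, an AP-1 subunit, stood at 1.29 (1.24 to 1.33) in macrophage-like and 1.62 (1.56 to 1.68) in CD8 T-like cells. Hspa1a, an inducible heat shock chaperone, was at 3.27 (3.07 to 3.48) in macrophage-like cells, against 3.99 in the other classes, and 3.99 (3.10 to 5.03) in dendritic-like cells.

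The second comparison asked how macrophage-like cells differed between the times. Inflammatory cytokine genes were higher at 4 weeks: Il1b, which encodes interleukin-1 beta, at 0.89 (0.84 to 0.95), Il1a at 3.14 (2.77 to 3.52), and Tnf, which encodes tumour necrosis factor, at 1.93 (1.75 to 2.11). The inhibitor Tnfaip3, a brake on NF-kappaB, lay at 2.01 (1.81 to 2.203), the interleukin-1 receptor antagonist Il1rn at 0.64 (0.56 to 0.71) and the neutrophil attractant Cxcl2 at 0.84 (0.79 to 0.88). In the inflammatory list 11 of 14 measured members were at least 1.5 times higher at 4 weeks, 1 at least 1.5 times lower and 2 in between, and these bounds are used for every list below. The median log2 ratio was 0.80, at percentile 99.94 of 10000 random lists matched on expression. Minus the median of the other classes, over 6 members, the median was 0.63, and with trimmed-mean factors it was 0.37. Socs3, the feedback inhibitor of cytokine signalling, on chromosome 11 from 117966079 to 117970047 of mm10 (ENSMUSG00000053113), stood at 2.78 (2.70 to 2.87), against 2.59 in the other classes.

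Several chemokine genes were lower in macrophage-like cells at 4 weeks. Ccl8, a monocyte and T cell attractant (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799, plus strand), was at -2.82 (-2.90 to -2.74), with 2647 CPM at 2 weeks and 376 CPM at 4 weeks (CPM of the class total). Cxcl9, an interferon-gamma-induced T cell attractant, lay at -1.14 (-1.203 to -1.07) and the monocyte attractant Ccl2 at -0.77 (-0.82 to -0.71). Higher at 4 weeks were the B cell attractant Cxcl13 at 1.29 (1.11 to 1.46) and the eosinophil attractant Ccl24 at 1.40 (1.14 to 1.65). In the chemokine list 22 members were measured, of which 7 were higher, 9 lower and 6 in between, and the median was -0.32 (percentile 0.13). The direction of that median turned to 0.67 minus the other classes, which covered only 4 members, and the median was -0.060 with each library clustered on its own and -0.75 with trimmed-mean factors. Ccl4, one of the 4 members, stood at 0.91 (0.84 to 0.99) against -0.78 in the other classes. Cells with a Cxcl9 UMI made up 46.6% (44.3 to 49.0) at 2 weeks and 23.9% (19.9 to 28.2) at 4 weeks after thinning, and 75.7% and 44.5% without it. In B cell-like cells, which should lack it, the shares were 2.29% and 0.176% after thinning and 10.3% and 1.14% without it.

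Genes of antigen presentation on MHC class II, which shows peptides to CD4 T cells, were compared next. Cd74, the invariant chain, was at -0.40 (-0.41 to -0.39), H2-Aa at -0.45 (-0.47 to -0.43), H2-Ab1 at -0.41 (-0.43 to -0.39) and H2-DMb2 at -1.11 (-1.24 to -0.99). In the class II list 2 of 10 measured members were higher, 1 lower and 7 in between, with a median of -0.40 at percentile 0.39. The median of these genes over the other classes was -0.33, although it was -0.014 in plasmacytoid dendritic-like cells alone. Minus the other classes the macrophage-like median was -0.11, while it was -0.84 with trimmed-mean factors. The interferon-gamma list had members on both sides: the median was 0.51 at percentile 99.90, with 10 of 22 members higher, 2 lower and 10 in between. The percentile was 94.8 among lists matched on transcript length as well, and minus the other classes the median was 0.023 (percentile 28.7), so this difference was largely shared. Irf1, one of its transcription factors, lay at 1.13 (1.04 to 1.21), the peptide transporter Tap1 at 1.48 (1.36 to 1.60) and the immunoproteasome subunit Psmb8 at -0.48 (-0.53 to -0.43).

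Complement genes of macrophages parted in direction. C1qa, C1qb and C1qc, the subunits of C1q, stood at -0.84, -0.79 and -0.88, while Cfb, complement factor B, was at 1.64 (1.503 to 1.77). In the complement list 14 members were measured, of which 3 were higher, 4 lower and 7 in between, and the median was -0.051 (percentile 13.2). Pf4, a chemokine of resident macrophages, lay at 1.14 (1.02 to 1.26) and Folr2, a folate receptor of perivascular macrophages, at -1.60 (-2.02 to -1.22). In the list of resident and scavenger genes 2 of 13 measured members were higher, 3 lower and 8 in between, with a median of 0.073 at percentile 31.9. Apoe, the lipid carrier, stood at -0.23 (-0.25 to -0.22), the protease Ctsb at -0.33 (-0.37 to -0.30) and 0.040 minus the other classes, Lgals3 at 0.010 (-0.018 to 0.038) and Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, at -1.71 (-2.87 to -0.75). In the lipid and lysosome list the median was -0.044 at percentile 44.4, with 0 of 17 members higher, 2 lower and 15 in between, and minus the other classes the median turned to 0.083.

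Of the genes ranked by size, the highest at 4 weeks in macrophage-like cells included Pmaip1, a proapoptotic factor, at 3.30 (2.96 to 3.64) against 2.56 elsewhere, Plau, which encodes urokinase, at 2.89 (2.65 to 3.14) and the transcription factor Klf10 at 2.88 (2.63 to 3.14) against 2.83 elsewhere. The lowest included Saa3, an acute-phase protein, at -1.95 (-2.202 to -1.71), the metallothionein Mt2 at -1.72 (-2.09 to -1.37), Wfdc17 at -1.41 (-1.497 to -1.32) and Ly6a at -1.27 (-1.32 to -1.23) against -1.22 elsewhere. Genes that stood apart from the other classes, chosen after their values were seen, were the lectin Mgl2 at 1.05 (0.79 to 1.30) against -0.93 elsewhere, the fractalkine receptor Cx3cr1 at 1.92 (1.72 to 2.12) against 0.31, and Cd38 at -1.08 (-1.38 to -0.79) against 0.31. Macrophage-like cells spread over clusters 0, 1, 2 and 14, which held 39.8%, 18.6%, 36.1% and 5.52% of the class at 2 weeks and 25.8%, 25.5%, 23.9% and 24.8% at 4 weeks.

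Monocyte-like and dendritic-like cells were compared in the same way. In monocyte-like cells the class II genes Cd74, H2-Aa, H2-Ab1 and H2-DMb2 were at -0.46 (-0.48 to -0.44), -0.59 (-0.62 to -0.56), -0.53 (-0.56 to -0.50) and -1.44 (-1.67 to -1.201). In the class II list 8 members were measured, of which 0 were higher, 3 lower and 5 in between, and the median was -0.51 (percentile 0.02). Lower at 4 weeks were the chemokine genes Ccl12 at -1.94 (-2.37 to -1.53), Cxcl9 at -1.49 (-1.75 to -1.23) and Ccl5 at -1.32 (-1.51 to -1.13), and the interferon-induced AW112010 at -2.01 (-2.10 to -1.91). Higher was Tlr2, a receptor for bacterial lipoproteins, at 1.98 (1.63 to 2.34). The interferon-gamma list had a median of 0.26, with 7 of 21 members higher and 4 lower. Psmb8 lay at -0.63 (-0.73 to -0.52), Psmb9 at -0.65 (-0.80 to -0.49) and Tap1 at 1.47 (1.18 to 1.76). Irgm1 stood at 1.5002 (1.00 to 2.01), and at -0.17 minus the other classes. The list median turned to -0.050 with trimmed-mean factors and -0.11 with median-of-ratios factors, and to -0.27 minus the other classes. Spp1, which encodes osteopontin, was at 1.14 (0.78 to 1.51) and turned to -0.82 at the finer clustering.

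In dendritic-like cells, which prime T cells, several interferon-response genes were lower at 4 weeks. Cxcl10, a T cell attractant (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889, minus strand), lay at -2.90 (-3.85 to -2.08) and Cxcl9 at -2.04 (-2.33 to -1.77). Isg20 and Isg15, antiviral effectors, stood at -2.197 (-4.18 to -0.67) and -0.93 (-1.27 to -0.60), and Bst2, a virus-tethering protein, at -0.97 (-1.19 to -0.76). Ifi27l2a was at -0.041 (-0.20 to 0.12), Ifi47 at -1.51 (-1.90 to -1.14) and Psmb8 at -0.67 (-0.78 to -0.56). In the type I interferon list 0 of 13 measured members were higher, 6 lower and 7 in between, with a median of -0.42 at percentile 0.92, and minus the other classes the median was -0.62 over 12 members. In the interferon-gamma list the median was -0.041 at percentile 38.7, with 4 of 21 members higher, 6 lower and 11 in between, and minus the other classes it was -0.64. Tap1 was higher at 4 weeks, at 1.58 (1.22 to 1.94), as it was in the other classes where it is given here. Plet1 lay at -2.88 (-3.92 to -1.99), Ly6a at -2.22 (-2.36 to -2.08) and the serpin Serpina3g at -2.08 (-2.38 to -1.80). In plasmacytoid dendritic-like cells, the main producers of type I interferon, the same list lay on the other side: 7 members were measured, of which 3 were higher, 0 lower and 4 in between, and the median was 0.53 (percentile 97.3). Isg15 stood at 1.54 (0.66 to 2.51), Irf7, the master regulator of interferon production, at 0.61 (0.32 to 0.91), Ifi27l2a at 0.53 (0.36 to 0.69) and Bst2 at -0.35 (-0.43 to -0.27), which turned to 0.23 minus the other classes. The difference between the 2 dendritic classes was not tested. Ly6d and Cd8a were at -1.60 and -1.43 in plasmacytoid dendritic-like cells.

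The third comparison asked how T-like and NK-like cells differed between the times. In CD8 T-like cells several cytotoxic genes were lower at 4 weeks: Gzmb, which encodes granzyme B (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260, minus strand), lay at -1.02 (-1.07 to -0.96), Gzma at -1.69 (-1.90 to -1.48), and the perforin gene Prf1 at -1.03 (-1.31 to -0.76). Nkg7 at -0.46 (-0.48 to -0.43) and the chemokine Ccl5 at -0.048 (-0.068 to -0.028) differed by less than 1.5 times. In the cytotoxic list 1 of 13 measured members were higher, 6 lower and 6 in between, with a median of -0.46 at percentile 0.01. The list median was -0.17 with each library clustered on its own and -0.78 with trimmed-mean factors. It turned to 0.54 minus the other classes, over 6 members, where Nkg7 stood at 0.38 and Ccl5 at 0.75. Prf1 turned to 0.72 when each library was clustered on its own, and Gzma to 0.54 without proliferating cells. That last setting left out 94.6% and 93.8% of the class at 2 and 4 weeks. Without only the cells holding at least 2 UMIs over 10 cycle genes, 0 of 293 gene values over all classes turned.

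Several receptors of activated T cells were lower at 4 weeks as well. Lag3, Pdcd1 and Tnfrsf9 were among the leading genes of cluster 6, which held 41.5% of the class at 2 weeks and 11.8% at 4 weeks. The ratios of the class therefore do not part the mix of clusters from the level per cell. Pdcd1, which encodes PD-1, was at -0.93 (-1.01 to -0.85), Lag3 at -1.07 (-1.16 to -0.99), the costimulatory receptor Tnfrsf9 at -1.07 (-1.197 to -0.94), Cd160 at -1.68 (-1.95 to -1.42) and the transcription factor Tox at -0.56 (-0.81 to -0.31). Higher were the early activation marker Cd69 at 1.33 (1.19 to 1.46) and the inhibitory receptor Ctla4 at 1.18 (0.97 to 1.39). In the activation and exhaustion list the median was -0.17 at percentile 7.42, with 4 of 14 members higher, 4 lower and 6 in between. With each library clustered on its own, where the class held 14.2% of cells at 2 weeks, these directions turned: Lag3 lay at 0.56, Tnfrsf9 at 3.86, Cd160 at 1.21 and Tox at 1.52. Pdcd1 stood at 1.35 minus the other classes, and Ctla4 at -0.017 without proliferating cells, a setting that left few cells of the class.

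Genes of the interferon-gamma response were higher in CD8 T-like cells at 4 weeks. Tap1 was at 1.58 (1.39 to 1.79), the guanylate-binding protein Gbp2 at 1.37 (1.01 to 1.73) and Irf1 at 1.18 (1.02 to 1.35). Psmb8 lay at -0.22 (-0.28 to -0.17) and at 0.19 minus the other classes, and its partner Psmb9 at -0.40 (-0.48 to -0.32) and 0.13. Ifi47, an interferon-induced GTPase, stood at 0.17 (0.035 to 0.31) and turned to -0.15 with trimmed-mean factors and -0.33 with each library clustered on its own. In this list 20 members were measured, of which 12 were higher, 2 lower and 6 in between, and the median was 1.08 (percentile 99.99), and minus the other classes the median was 0.45 over 20 members. It was 0.68 with each library clustered on its own. Over 10 members it was 0.22 without proliferating cells, a setting that left few cells of the class. Cxcl9 and Cxcl10 are counted in the list, but their level in this class lay under 0.25 of the library's and is read as free RNA.

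Several glycolytic genes were lower in CD8 T-like cells, with Pgk1 at -1.64 (-1.93 to -1.36), Tpi1 at -1.09 (-1.22 to -0.97) and Gapdh at -0.46 (-0.52 to -0.41). Eno1 was at -0.52 (-0.58 to -0.45), and Aldoa at -0.58 (-0.64 to -0.52) and 0.047 minus the other classes. In the glycolysis and hypoxia list 3 of 13 measured members were higher, 4 lower and 6 in between, with a median of -0.52 at percentile 0. The other classes had a median of -0.37 in this list, and minus those it was -0.091 (percentile 13.7). Naive and memory genes, with Lef1 at 1.80 (1.24 to 2.40), had a median of 0.73 at percentile 96.6, which was -0.028 minus the other classes, and proliferation genes one of 0.0099 at percentile 3.36. By size, the highest genes included Klf10 at 4.02 (3.42 to 4.68), the kinase Sgk1 at 3.35 (2.91 to 3.81) and Txnip at 2.76 (2.54 to 2.997). The other classes had 2.75, 2.64 and 1.83 for these genes in that order. The lowest included Tnfrsf4, which encodes OX40, at -1.98 (-2.30 to -1.66) and the chemokine Xcl1 at -1.36 (-1.44 to -1.28), which turned to 1.85 and 3.72 with each library clustered on its own. Metallothionein Mt1 lay at -1.87 (-2.06 to -1.69). Genes apart from the other classes, chosen after their values were seen, were the receptor Klrc1 at 1.505 (1.43 to 1.59) against 0.24, the transcription factor Rora at 2.14 (1.83 to 2.45) against 0.68, and Tbx21, which encodes T-bet, at 1.26 (1.05 to 1.46) against -0.039. Different clusters held most of this class: clusters 6 and 8 held 41.5% and 53.7% of it at 2 weeks, and cluster 20 held 77.2% at 4 weeks.

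In shares of cells with a UMI, compared after thinning each cell to 1000 UMIs, CD8 T-like cells with a Gzmb UMI made up 42.7% (39.7 to 45.7) at 2 weeks and 28.1% (25.7 to 30.6) at 4 weeks after thinning, and 61.1% and 42.2% without it. Cells with a Pdcd1 UMI made up 42.3% (39.3 to 45.4) at 2 weeks and 23.7% (21.5 to 26.1) at 4 weeks after thinning, and 72.9% and 46.3% without it, and cells with an Ifng UMI 30.1% (27.4 to 33.0) at 2 weeks and 26.0% (23.6 to 28.4) at 4 weeks after thinning, and 58.4% and 50.1% without it. In B cell-like cells, which should lack these genes, Gzmb UMIs were found in 0.571% and 0.880% after thinning and 3.43% and 2.37% without it, Pdcd1 UMIs in 0% and 0.264%, and 3.43% and 1.67% without it. Ifng UMIs were found in 1.14% and 0.616% of them, and 3.43% and 2.37% without thinning.

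In CD4 T-like cells 2 of 8 measured regulatory T cell markers were higher at 4 weeks: Foxp3, their lineage factor (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand), stood at 2.07 (1.42 to 2.76) and Ikzf2, which encodes Helios, at 1.94 (1.55 to 2.35). Il10, an immunosuppressive cytokine, was at -2.94 (-4.04 to -2.01), Tnfrsf4 at -0.91 (-1.05 to -0.76) and Tnfrsf18 at -0.37 (-0.52 to -0.22), which turned to 0.19 minus the other classes. In the regulatory list the median was 0.0078 at percentile 76.9, with 2 of 8 members higher, 2 lower and 4 in between, and the median was -0.63 with each library clustered on its own and -0.25 with trimmed-mean factors. Cells with a Foxp3 UMI made up 2.48% (0.915 to 5.32) at 2 weeks and 7.10% (3.84 to 11.8) at 4 weeks after thinning, and 7.02% and 21.3% without it, against 0% in B cell-like cells at both times. The median depth of CD4 T-like cells was 4062 and 3316 UMIs. With each library clustered on its own Foxp3 turned to -1.39. Capg, an actin-capping protein, lay at -0.19 (-0.36 to -0.024) and 0.35 minus the other classes. Of the helper genes, Gata3 stood at 1.56 (1.1999 to 1.93), Tnf at 1.27 (0.70 to 1.85), Il2 at -1.51 (-2.05 to -1.01) and Ifng at -0.35 (-0.54 to -0.16), which turned to 0.059 with each library clustered on its own. In the helper list 8 members were measured, of which 2 were higher, 3 lower and 3 in between, and the median was -0.25 (percentile 4.02).

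The cytotoxic list had a median of -0.51 in CD4 T-like cells, with Ccl5 at -1.66 (-1.92 to -1.40) and Nkg7 at -0.83 (-0.94 to -0.72). By size, granzyme C (Gzmc) was at 4.92 (3.65 to 6.57), Tnfsf11, which encodes RANKL, at 2.76 (2.24 to 3.32), the gut-homing integrin Itgb7 at 2.37 (1.95 to 2.81), Ccl4 at -1.39 (-1.52 to -1.27) and Ccl1 at -1.96 (-2.18 to -1.75). Xcl1 lay at -3.67 (-4.60 to -2.87) and turned to 2.66 with each library clustered on its own and 2.05 without doublet removal.

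Cluster 7 had lower cytotoxic genes at 4 weeks. Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518, minus strand) stood at -2.41 (-2.54 to -2.28), Gzma at -4.06 (-5.33 to -2.95), Gzmk at -3.05 (-4.35 to -1.82), Gzmb at -2.03 (-3.27 to -0.74), Nkg7 at -1.43 (-1.62 to -1.23) and Cst7 at -1.56 (-2.202 to -0.90). In the cytotoxic list 0 of 8 measured members were higher, 8 lower and 0 in between, with a median of -1.79 at percentile 0, and minus the other classes the median was -1.01. Cxcr3, a receptor of effector T cells, was at -1.86 (-2.45 to -1.26), Lag3 at -2.61 (-3.63 to -1.60) and Pdcd1 at -2.28 (-3.39 to -1.16). Naive and memory genes had a median of 0.39, which turned to -0.13 minus the other classes. Lef1 and Klf2, factors of naive T cells, lay at 1.205 (0.76 to 1.68) and 0.42 (0.24 to 0.60), and at -0.31 and -0.19 minus the other classes. Satb1 and Ccr7, genes of the same cells, stood at 1.13 (0.61 to 1.70) and 0.36 (0.023 to 0.71). Cells with a Ccr7 UMI made up 22.4% (13.6 to 33.4) at 2 weeks and 33.4% (28.7 to 38.4) at 4 weeks after thinning, and 43.4% and 65.3% without it, against 0% and 1.16% of NK-like cells after thinning and 3.51% and 4.07% without it. Median depths were 2933 and 3111 UMIs in cluster 7 and 2961 and 2838 in NK-like cells. With each library clustered on its own, no cluster of the 2-week library was left unnamed with T cell markers, as cluster 7 was. Whether the 76 cells that cluster 7 held at 2 weeks then lay in a cluster with another name was not examined.

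In NK-like cells the cytotoxic genes parted in direction. Gzmb was at -1.34 (-1.52 to -1.17), Gzmk at -2.15 (-3.95 to -0.64) and Ifng at -1.04 (-1.36 to -0.73), while Gzmc lay at 2.18 (1.38 to 3.07) and Ccl5 at 0.41 (0.34 to 0.48). Gzma and Nkg7, with the most UMIs of the list, stood at -0.33 (-0.42 to -0.25) and -0.039 (-0.15 to 0.073). The share of NK-like cells with an Ifng UMI went the other way than its ratio, with 8.77% (4.29 to 15.5) at 2 weeks and 17.4% (12.1 to 24.0) at 4 weeks after thinning, and 21.1% and 33.7% without it. In the cytotoxic list the median was -0.041 at percentile 78.5, with 1 of 13 members higher, 4 lower and 8 in between, and minus the other classes it was 0.57 over 6 members, while the list was at 0.059 with each library clustered on its own. The chemokine gene Ccl3 lay at 1.75 (1.39 to 2.12). Mast cell protease genes were found at 2 weeks: Cma1 stood at -3.26 (-4.27 to -2.38), and Cpa3 at 214 CPM at 2 weeks and 0 at 4 weeks, which is at least 39.3-fold lower against a floor of 3 counts. Ifitm1, an interferon-induced membrane protein, was at -4.23 (-6.15 to -2.79) and Cd63, a protein of secretory granules, at -2.74 (-3.83 to -1.79). Since mast cell genes were found in this class at 2 weeks, whether the Ifitm1 and Cd63 differences lie in NK cells was not tested.

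The fourth comparison asked how B cell-like cells differed. Genes of lymphoid follicles were higher at 4 weeks: S1pr2, a confinement receptor of germinal centre B cells, lay at 1.94 (1.21 to 2.76), Cxcr5, the follicle-homing receptor (ENSMUSG00000047880, chromosome 9, 44511787 to 44561877, minus strand), at 1.57 (1.09 to 2.09), and Cr2, a complement receptor, at 1.18 (0.71 to 1.69). In the follicle list 9 members were measured, of which 6 were higher, 1 lower and 2 in between, and the median was 1.14 (percentile 99.90), and minus the other classes, over 4 members, the median was 0.38. Fcer2a, the low-affinity receptor for IgE, stood at 0.70 (0.47 to 0.94). Ltb, which encodes lymphotoxin beta, was at 0.14 (0.042 to 0.24) and turned to -0.075 with trimmed-mean and -0.093 with median-of-ratios factors. The B cell receptor subunit gene Cd79a lay at -0.14 (-0.21 to -0.073), which was 0.054 with each library clustered on its own. Its partner Cd79b stood at 0.20 (0.11 to 0.29) and turned to -0.018 and -0.035 with the same factors. Ms4a1, which encodes CD20, was at 0.59 (0.47 to 0.71) and the inhibitory receptor Cd22 at 1.24 (0.87 to 1.62). In the receptor list 4 of 13 measured members were higher, 2 lower and 7 in between, with a median of 0.27 at percentile 96.7, and its direction turned to -0.57 minus the other classes, over 4 members.

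Presentation genes of MHC class I, which shows peptides to CD8 T cells, parted in direction in B cell-like cells. H2-K1 and H2-D1, the heavy chains, lay at -1.10 (-1.19 to -1.02) and -0.63 (-0.68 to -0.58), and B2m, their light chain, at -0.95 (-1.01 to -0.90). The other classes had -0.71 for H2-K1 and -0.55 for B2m, so these were shared in part, and both lay outside the B cell-like intervals. Tap1 and Tap2, which carry peptides to them, stood at 1.42 (0.87 to 2.03) and 1.75 (1.10 to 2.48), and Tap1 turned to -0.048 minus the other classes. In the class I list the median was -0.25 at percentile 0.20, with 4 of 12 members higher, 5 lower and 3 in between, and minus the other classes it was -0.36 (percentile 0). By size, Dusp6, a phosphatase of ERK, was at 3.49 (2.43 to 4.81), Cxcr4, a receptor of germinal centre and bone marrow homing, at 2.73 (2.04 to 3.52), Ppp1cb at 3.58 (2.45 to 5.04) and Cfp, complement properdin, at -2.32 (-2.73 to -1.91). The other classes had 2.06, 1.935, 1.665 and -0.21 for these genes in that order. Egr1, an immediate early factor downstream of the B cell receptor, lay at -0.53 (-0.87 to -0.18) against 1.65 in the other classes and was singled out after its values were seen. Of the B cell-like cells, 24 of 175 at 2 weeks and 202 of 1137 at 4 weeks lay in cluster 16, led by Rgs13, and the others in cluster 9. Immunoglobulin and T cell receptor constant genes were not analysed here.

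**Figure D3:**
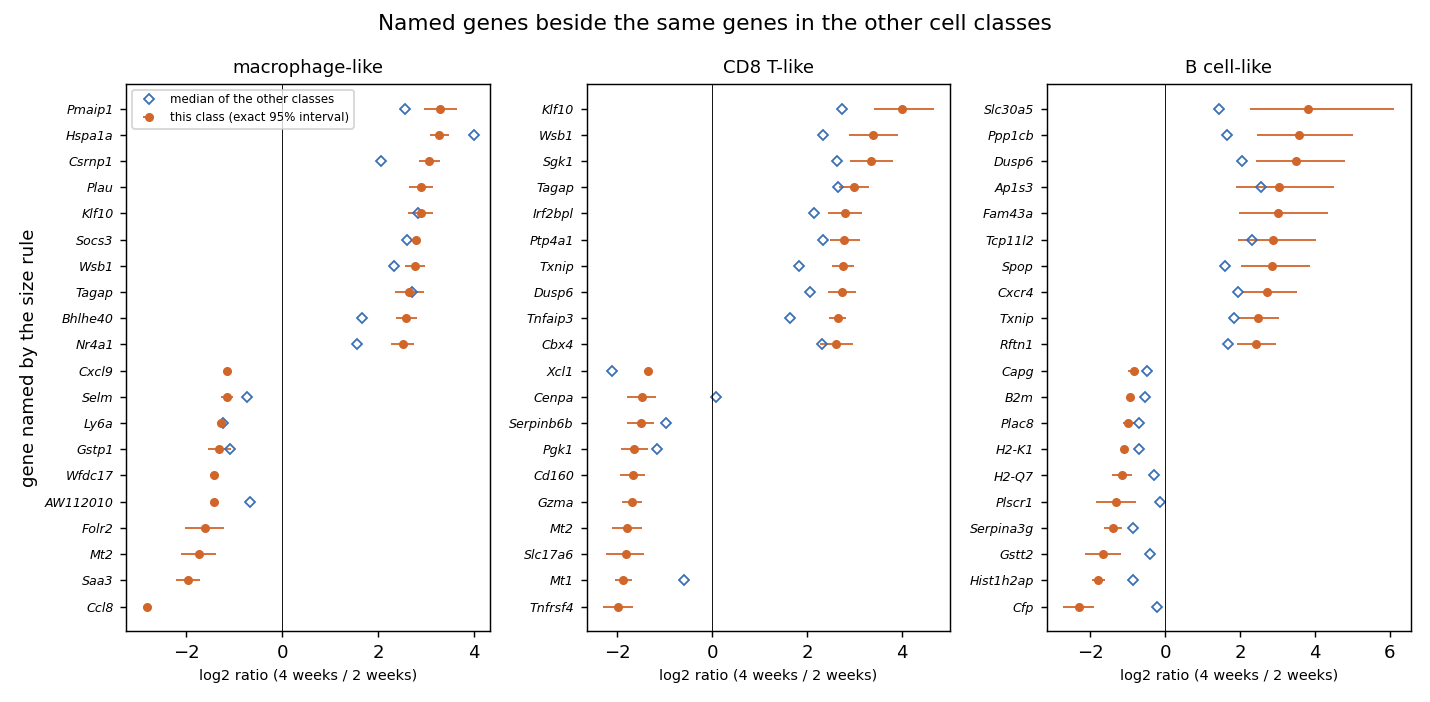
Log2 ratio of 4 weeks over 2 weeks (horizontal axis) of the 20 genes ranked by size in macrophage-like, CD8 T-like and B cell-like cells, with exact 95% intervals that cover counting error only, beside the median of the same gene in the other compared classes (open diamonds, where at least 3 of them express it). Klf10 in CD8 T-like cells stands at 4.02 against 2.75 elsewhere, and Cfp in B cell-like cells at -2.32 against -0.21.

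Cycling cells, counted as cells with at least 2 UMIs over 10 mitotic genes after thinning, were most frequent in the other T-like class. Among B cell-like cells they made up 7.43% (4.01 to 12.4) at 2 weeks and 4.31% (3.21 to 5.66) at 4 weeks, and without thinning 12% and 9.59%. Among CD8 T-like cells they made up 0.285% (0.0588 to 0.831) and 0.377% (0.122 to 0.876), and without thinning 5.04% and 2.64%. Among macrophage-like cells the shares were 0.442% and 0.464%, and 3.59% and 4.87% without thinning. Among plasma cell-like cells they made up 14.3% (3.05 to 36.3) of 21 cells at 2 weeks and 4.92% (1.03 to 13.7) of 61 at 4 weeks, and without thinning 33.3% and 16.4%. In the other T-like class, cluster 10, led by the mitotic genes Stmn1, Birc5 and Ccnb2, they made up 69.4% (57.5 to 79.8) and 78.3% (56.3 to 92.5). That class took 1.73% at 2 weeks and 0.523% at 4 weeks of all kept cells, a difference that turned to 5.02 (3.72 to 6.33) percentage points with each cell assigned alone. The set of 10 genes was chosen after the data were seen, since the wider list fixed at the start marked 43.9% and 47.8% of CD8 T-like cells after thinning and 94.6% and 93.8% without it.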

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

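Both searches reported here, of barcodes left out by the doublet step and by the cell filter, were chosen after the results were seen.

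Contractile smooth muscle genes stood out among barcodes that entered no comparison. Of the 202 barcodes removed as doublets at 2 weeks, 18 held at least 5 of these genes (8.91%, 5.37 to 13.7). At 4 weeks 0 of 190 did, which allows a share of up to 1.58%. Among kept cells 4 of 4164 at 2 weeks (0.0961%, 0.0262 to 0.246) and 9 of 4395 at 4 weeks (0.205%, 0.0937 to 0.388) held as many, so cells with these genes were not absent at 4 weeks. Without doublet removal 7 cells at 2 weeks and 3 at 4 weeks fell in a smooth muscle-like class.

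Haemoglobin stood out among barcodes removed by the cell filter. At 4 weeks 21 of 30 such barcodes had over 10% haemoglobin UMIs, against 0 of 8 at 2 weeks. Haemoglobin made up 82.9% of the UMIs of the removed 4-week barcodes, although the sort was for nucleated cells.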

How the results depend on the processing

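Chosen after the results were seen were the common UMI minimum, the subtraction of the other classes, the variable genes without those that differed in the median over classes, and the set of 10 cycle genes. No paired analysis was possible because each time has 1 library. Depth limits the smaller classes most: in the simulated data 74.6% of genes altered 2-fold were recovered in cluster 7 and 100% in macrophage-like cells. Without proliferating cells few genes and lists gave a value, because the list fixed at the start marked most cells as proliferating. Of the alternative values, 168 of 193 for class shares, 434 of 576 for list medians, 2753 of 3619 for named genes and 48 of 64 for shares of cells with a UMI stayed within the counting interval of the reported value. Direction turned for 2 class shares, 14 list medians, 52 gene values and 1 share of cells with a UMI, counted where the interval of the reported value excluded 0, and the others moved with their direction kept or with no direction called. Scaling factors move all ratios of a class by the same amount, and the subtraction removes what other classes share by construction. For every other value that follows the cause was not tested. Shares and medians whose direction turned are marked, and every gene value below turned.

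With each library clustered on its own, the difference in share was 19.6 points for B cell-like cells, -2.79 points for CD4 T-like cells, 16.2 points for CD8 T-like cells, -28.9 points for macrophage-like cells, -6.32 points for monocyte-like cells and 8.74 points for cluster 7. No 4-week cluster was then named monocyte-like and no 2-week cluster carried the unnamed T cell label of cluster 7. The values for these classes are therefore the whole share of the other library. Here the list medians were regulatory T -0.63 in CD4 T-like cells, and cytotoxic effector -0.17 and interferon-gamma response 0.68 in CD8 T-like cells. Medians were cytotoxic effector 0.059 in NK-like cells, and inflammatory macrophage 0.70, chemokines -0.060 and MHC class II presentation -0.32 in macrophage-like cells. Here the genes stood at Cd79a 0.054 in B cell-like cells, and Xcl1 2.66, Foxp3 -1.39 and Ifng 0.059 in CD4 T-like cells, and Tnfrsf4 1.85, Slc17a6 2.90, Cd160 1.21, Xcl1 3.72, Cenpa 0.088, Prf1 0.72, Lag3 0.56, Tnfrsf9 3.86, Tox 1.52 and Ifi47 -0.33 in CD8 T-like cells. With the UMI minimum of the other file, the difference in share was 16.7 points for B cell-like cells, 2.87 points for fibroblast-like cells and -31.8 points for macrophage-like cells. With each cell assigned alone, the difference in share was 0.00515 points for CD4 T-like cells (turned), -23.9 points for macrophage-like cells, -11.9 points for monocyte-like cells and 5.02 points for other T-like cells (turned). Without doublet removal, the difference in share was -0.489 points for CD4 T-like cells. Single genes were then at Xcl1 2.05 in CD4 T-like cells. At Leiden resolution 0.5, the difference in share was -35.5 points for macrophage-like cells. The list medians were inflammatory macrophage 0.71 and MHC class II presentation -0.35 in macrophage-like cells. With variable genes chosen without cycle, stress, mitochondrial and ribosomal genes, the difference in share was -1.02 points for monocyte-like cells. With at least 200 genes and at most 20% mitochondrial UMIs, the difference in share was -0.365 points for monocyte-like cells. Here the list medians were chemokines -0.26 in macrophage-like cells. With variable genes chosen without those that differed in the median over classes, the difference in share was -3.49 points for monocyte-like cells. Minus the median of the other classes, the list medians were lymphoid follicle 0.38, B cell receptor and activation -0.57 (turned) and immediate early and dissociation -0.32 (turned) in B cell-like cells, and regulatory T 0.27 in CD4 T-like cells. Medians were cytotoxic effector 0.54 (turned), interferon-gamma response 0.45 and naive and memory T -0.028 (turned) in CD8 T-like cells, and cytotoxic effector 0.57 and immediate early and dissociation -0.0072 (turned) in NK-like cells. Medians were inflammatory macrophage 0.63, chemokines 0.67 (turned), MHC class II presentation -0.11 and lipid and lysosome macrophage 0.083 (turned) in macrophage-like cells, and interferon-gamma response -0.27 (turned) and immediate early and dissociation -0.21 (turned) in monocyte-like cells. Medians were immediate early and dissociation -0.21 (turned) in plasmacytoid dendritic-like cells, and cytotoxic effector -1.01, naive and memory T -0.13 (turned) and immediate early and dissociation -0.41 (turned) in cluster 7. Here the genes stood at Tap1 -0.048 in B cell-like cells, and Tnfrsf18 0.19 and Capg 0.35 in CD4 T-like cells, and Xcl1 0.75, Ccl5 0.75, Nkg7 0.38, Psmb8 0.19, Pdcd1 1.35, Psmb9 0.13 and Aldoa 0.047 in CD8 T-like cells. Genes were Tagap -0.061 in NK-like cells, and Hspa1a -0.71, Tagap -0.046 and Ctsb 0.040 in macrophage-like cells, and Socs3 -0.59, Hspa1a -1.46, Klf10 -0.35, Pmaip1 -0.28, Zfp263 -0.032, Dusp6 -0.10 and Irgm1 -0.17 in monocyte-like cells. Genes were Tmem123 -0.046, Ly6a 0.30 and Bst2 0.23 in plasmacytoid dendritic-like cells, and Eef2 -0.060, Lef1 -0.31 and Klf2 -0.19 in cluster 7. With trimmed-mean factors, the list medians were regulatory T -0.25 in CD4 T-like cells, and cytotoxic effector -0.78 and interferon-gamma response 0.76 in CD8 T-like cells. Medians were inflammatory macrophage 0.37, chemokines -0.75 and MHC class II presentation -0.84 in macrophage-like cells, and interferon-gamma response -0.050 (turned) in monocyte-like cells. Single genes were then at Ltb -0.075 and Cd79b -0.018 in B cell-like cells, and Ifi47 -0.15 in CD8 T-like cells. With median-of-ratios factors, the list medians were regulatory T -0.33 in CD4 T-like cells, and cytotoxic effector -0.78 and interferon-gamma response 0.76 in CD8 T-like cells. Medians were inflammatory macrophage 0.35, chemokines -0.77 and MHC class II presentation -0.86 in macrophage-like cells, and interferon-gamma response -0.11 (turned) in monocyte-like cells. Here the genes stood at Ltb -0.093 and Cd79b -0.035 in B cell-like cells, and Ifi47 -0.15 in CD8 T-like cells. Without proliferating cells, the list medians were interferon-gamma response 0.22 in CD8 T-like cells. Single genes were then at Gzma 0.54, Ctla4 -0.017 and Ifi47 -0.086 in CD8 T-like cells. With at least 500 genes and at most 5% mitochondrial UMIs, the list medians were cytotoxic effector -0.78 in CD8 T-like cells. With mitochondrial and ribosomal genes out of the total, the list medians were cytotoxic effector -0.53 in CD8 T-like cells. With each cell weighed the same, the list medians were cytotoxic effector -0.51 in CD8 T-like cells, and inflammatory macrophage 0.68 in macrophage-like cells. With the top 8% of doublet scores removed, the list medians were chemokines -0.41 and MHC class II presentation -0.48 in macrophage-like cells. Without cells with 2 UMIs over 10 cycle genes, the list medians were chemokines -0.27 in macrophage-like cells. With at least 5 UMIs per member, the list medians were chemokines -0.26 in macrophage-like cells. At Leiden resolution 2.0, the list medians were MHC class II presentation -0.45 in macrophage-like cells. Here the genes stood at Spp1 -0.82 in monocyte-like cells. Without thinning, the difference in proliferating cells was -0.757 points for CD8 T-like cells. Here the difference in cells with a UMI was -5.00 points for Cd34 in fibroblast-like cells (turned). With at least 4 UMIs over the proliferation list, the difference in proliferating cells was -0.502 points for CD8 T-like cells.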

Other observations

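Chosen after their results were seen were the tests of transcript length, of depth, of the UMI minimum, of the smaller myeloid population, of blood and of time after grafting, and the counts in cluster 16. The predictions for the tests of free RNA and of the shared genes in CD8 T-like cells were set before the results of these tests were seen. The clustering without those genes was itself added after the data were seen. A test of depth by thinning, also set before, was dropped because thinning fixes its outcome.

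B cell-like cells held a cluster with germinal centre genes at both times. Cluster 16 had 257 and 584 CPM of Rgs13, a regulator of germinal centre B cells, at 2 and 4 weeks, against 7.10 and 2.65 in cluster 9, the other B cell-like cluster. Cd38, lower on germinal centre B cells of mice, had 21.4 and 9.06 CPM in cluster 16 against 90.6 and 104. At 2 weeks cluster 16 held 24 cells, with 60 UMIs of Rgs13, 5 of Cd38 and 2 of the follicle gene Bcl6. Its 10 leading genes held 3 B cell and 3 plasma cell markers. Cluster 16 made up 13.7% (8.99 to 19.7) of B cell-like cells at 2 weeks and 17.8% (15.6 to 20.1) at 4 weeks, intervals that overlap. Within B cell-like cells Ccr7, a receptor for homing to lymphoid tissue, had a log2 ratio of 0.86 (0.59 to 1.14).

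Gamma-delta T-like cells, an innate-like T lineage, made up 0.600% (0.389 to 0.885) at 2 weeks and 2.48% (2.04 to 2.98) at 4 weeks. That name rests on 3 detected markers, the minimum. The 10 leading genes held 1 marker of the T cell sets and 1 of innate lymphoid 2 cells, so other lymphoid lineages are not excluded. Among fibroblast-like cells a UMI of Cd34, a marker of adventitial progenitor cells, was found in 12.2% at 2 weeks and 39.7% at 4 weeks after thinning, but in 78.0% and 73.0% without it, so no order is read from these shares. In B cell-like cells the Cd34 shares were 0% and 0% after thinning and 0.571% and 0.352% without. Xist, the RNA of the inactive X chromosome, had a UMI in 0 of 1812 and 0 of 431 macrophage-like cells, and after thinning in 0 of 1052 CD8 T-like cells at 2 weeks and 4 of 1328 at 4 weeks (0.301%, 0.0821 to 0.769). The Y-linked Ddx3y had one in 14.2% and 17.2% of macrophage-like cells and, at 2 weeks, 21.4% of endothelial-like cells without thinning, so these genes did not part graft from host cells in those classes.

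The log2 ratios went together in all 9 compared classes: 88 of 1838 genes were at least 1.5 times higher and 4 lower in every class, with a median r between classes of 0.744 across genes. Free RNA from other cells is argued against only for genes expressed in every class. For 131 such genes that differed at least 2-fold in the median over classes, the CPM in the lowest class was a median 0.608 of the library's (quartiles 0.464 and 0.6999). These genes had at least 50 UMIs in every class, a minimum that leaves out many genes with little RNA of their own. That share follows in part from the minimum, and genes expressed in few classes are not covered. Lower UMI depth at 4 weeks is argued against as the whole cause by plasmacytoid dendritic-like cells and cluster 7. Their median depths were 5524 and 6121 and 2933 and 3111 UMIs at 2 and 4 weeks. Over 265 gene values in both, for genes that differed at least 2-fold in the median of the other classes, the log2 ratio was a median 0.876 of that median (quartiles 0.568 and 1.08). It was 0.91 of it in plasmacytoid dendritic-like cells and 0.79 in cluster 7, so a part played by depth is not excluded. A trend with transcript length as the whole cause is argued against by a median r of 0.685 (0.553 to 0.856) with the trend removed. A hypothesis is that handling of the 4-week graft or its library preparation may have shifted RNA in every cell type alike, which no value here tests. Time after grafting and the library cannot be told apart here, since each time is 1 library.

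B cell-like cells took a larger share at 4 weeks. A lower UMI minimum in the 4-week file is argued against as the whole cause. With the same minimum the difference was 16.7 percentage points (15.2 to 18.2), against 21.7 as reported, so a part played by the minimum is not excluded. A smaller macrophage and monocyte population is argued against as the whole cause, since outside those classes the share was 8.41% and 30.2%, a ratio of 3.59. Blood carried over could add B cells: 22 barcodes at 4 weeks were erythroid (0.299 to 0.721% of 4615) and 0 of 4374 at 2 weeks, which allows up to 0.0686%. Blood and recruitment to the graft cannot be told apart for the cells of cluster 9, since germinal centre genes mark only cluster 16.

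CD8 T-like cells lay in other clusters at 4 weeks than at 2 weeks, with a distance of 78.2% between the 2 distributions over clusters. Clustered without 3550 genes that differed in the median over all classes, the distance was 29.9%, and without as many random genes matched on expression it was 93.04%. The 3550 genes were picked because they differed between the 2 libraries, with CD8 T-like cells among the classes of the median. A smaller distance follows in part from that choice, and the random genes were not matched on the difference. The unnamed class with T cell markers is the single cluster 7, so its distance of 0% with no genes left out was fixed in advance. There the distance was 23.7% without the 3550 genes and 41.9% without the random ones, and no change from 0% is read. In B cell-like cells the distance stayed at 4.05%, 4.05% and 3.96% in that order. Because of how the 3550 genes were picked, the fall in CD8 T-like cells cannot assign the split to genes shared by classes or to CD8 T-like cells alone. Time after grafting and the library cannot be told apart as the origin of the split.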
